A study of Arabidopsis thaliana with 2 samples.

How the data were processed

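RNA of seedlings of 2 genotypes was labelled with biotin and hybridised to Affymetrix arrays, 1 array per genotype. Per the labels and the series' design text, seedlings were genotyped by PCR one by one before RNA extraction, were grown for 7 days on sugar-containing medium and received no treatment. How many seedlings stand behind each array is not given in the sources used here. The deposited table holds log2 values of 22810 probe sets on each array, made by the authors with RMA, per the submitters' processing notes. The version of RMA and the software are not given in the sources used here. That the values are on the log2 scale was read from their range, 2.39 to 14.3, since no label states it. RMA puts the arrays on one distribution of probe intensities and summarises each probe set over its probes, so a change shared by most genes would not be seen. Exactly equal values, with no rounding applied here, were found on both arrays for 394 of the 22810 probe sets.

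Groups were taken from the sample titles. Of the 22810 probe sets, 64 are Affymetrix controls and were kept out of every count and list. Genes were named from the platform annotation given with the table, which can be old, through its gene identifiers to a RefSeq gene table of the TAIR10.1 assembly. It lists 13513 probe sets with 1 gene, 503 with several and leaves 8730 gene probe sets unnamed here. Of those with 1 gene, 13436 matched a RefSeq gene and 77 did not, and a locus code was had for 13333 different loci. Many genes with common symbols are among the unnamed, so 105 of the 557 nuclear loci in the gene lists could be measured. Genome coordinates are not printed, because no build is named for the probe sets.

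Each difference is the triple minus the double expressor on the log2 scale. With 1 array per group no model was fitted. The first result is the number of probe sets at least 2-fold apart whose brighter array is at or above the 40th percentile of all values, a floor of 5.71. The second is the median difference of each of 39 gene lists, with 1 probe set per locus, the one with the highest mean. The median's percentile among 10000 random lists of the same size, matched on mean level in 20 bins, was given for the 17 lists with at least 3 named members. Another 13 lists had 1 or 2 named members and 9 had none: oxygen sensing machinery, extensins, ferritins, salicylate defence, phosphate starvation, nitrate response, brassinosteroid, RNA silencing and mitochondrion-encoded genes. Chloroplast genes were taken by the chromosome in the RefSeq table, since its plastid locus codes differ from those planned. A 95% order-statistic interval of the median over the 17 hypoxia genes was computed from the binomial distribution.

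The lists, the floor, the alternatives and the rule for named genes were fixed before the data were examined. The rule names, among probe sets of 1 nuclear gene above the floor and at least 2-fold apart, the 12 highest and the 12 lowest (5 qualified), a fixed set of 11 hypoxia genes and 4 reference genes, of which 3 had a named probe set, the prolyl 4-hydroxylases, and up to 4 members per list by size of difference. EXO, the only probe set left over, DFR, the fifth of the 5 flavonoid genes, and AT2G17850, the lowest hypoxia gene, were named beyond that rule after their values were seen. Alternatives were centring each array on its median, centring on a lowess curve of the difference against the mean (span 0.3), no floor or a floor at the 60th percentile, a 1.5-fold threshold, leaving out probe sets whose names mark cross-hybridisation, the mean of all probe sets per locus, random lists that were not matched, and a damped scale with 32 added to the unlogged values. The damped scale was applied to the counts and to single genes, not to list medians. Gene families grouped by symbol were examined after the lists.

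The procedure was tested on simulated data with independent, normally distributed noise that had the spread of the real differences at each level. The 200 changed probe sets among 22746 were drawn from those with a mean at least 1 above the floor. Of those changed by 1.5 on the log2 scale 99.0% passed the 2-fold count, as did 53.0% of those changed by 1. Of 200 simulated lists of 17 loci drawn at random, 2.5% fell outside the central 95%, and 88.5% of such lists shifted by 0.2 lay above it. Changes near the floor, outlying differences and co-regulated lists were not simulated. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Batches, array dates and detection calls were not used here.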

Results

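Gene expression was measured on 2 Affymetrix Arabidopsis arrays, each hybridised with RNA from untreated 7-day-old Col-0 seedlings that carry parts of a synthetic oxygen sensor. One array held RNA from the double expressor, whose seedlings express the fusion proteins that the labels name AD-HIFCOOD and GBD-pVHL. The other held RNA from the triple expressor, whose seedlings express both fusions together with PHD3. HIF is an animal transcription factor of the response to low oxygen, PHD3 is an oxygen-dependent prolyl hydroxylase that acts on it, and pVHL is the protein that binds hydroxylated HIF. The comparison of the 2 arrays therefore asks how the transcriptome of sensor seedlings with PHD3 differs from that of sensor seedlings without it. With 1 array per genotype there was no replicate spread, no test and no p-value, and every difference below compares these 2 arrays. The number of arrays limits the precision.

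The transcriptomes of the double and triple expressors were close to each other. Among 13896 probe sets with the brighter array at or above a log2 value of 5.71, 28 were at least 2-fold higher and 8 at least 2-fold lower in the triple expressor. The largest difference was that of AT1G11280, an S-locus lectin protein kinase, at 6.20 in the double and 8.11 in the triple expressor, a 3.76-fold higher level. AT1G05340, which encodes a small cysteine-rich membrane protein, was 2.74-fold higher. AT1G12400, a TFIIH subunit homologue, was 2.71-fold higher, and the histone H2B gene AT3G53650 was 2.48-fold higher. The zinc finger repressor gene STZ, which is induced by many stresses, went from 7.53 to 8.67, a 2.21-fold difference. AT4G34150, a C2-domain protein, went from 8.56 to 9.68. QQS, a regulator of starch content, was 2.17-fold higher. Both AT1G12010, a homologue of the ethylene-forming ACC oxidases, and AT1G06640, a dioxygenase dependent on 2-oxoglutarate and iron, were higher, by 1.13 and 1.04 on the log2 scale. AT3G06070, AT1G65490 and AT4G29780 were higher by 1.08, 1.05 and 1.02. EXO, a gene of brassinosteroid-promoted growth, was the only further probe set naming 1 gene past 2-fold, at 1.02. Of these 13 genes, EXO (0.99) and AT4G29780 (0.99) were under 2-fold after median centring, and AT4G29780 also after lowess centring. With 32 added to the unlogged values, 5 stayed past 2-fold: AT1G11280, AT1G05340, AT1G12400, STZ and AT4G34150.

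Fewer named genes were lower in the triple expressor, and 5 were lower by at least 2-fold. The U-box protein gene AT1G01670 went from 6.23 to 4.90, and PUB19, a U-box ubiquitin ligase of stress responses, from 6.21 to 5.03. AT1G02300, a cathepsin B-like cysteine protease, was 2.25-fold lower, at 8.82 in the double and 7.65 in the triple expressor. AT4G12490, a lipid transfer-like protein, was the brightest of these genes and was 2.18-fold lower, from 10.55 to 9.42. AT3G28320 went from 6.64 to 5.57. AT1G01670 and AT1G02300 lie in a stretch of chromosome 1 with the higher genes AT1G05340, AT1G06640, AT1G11280, AT1G12010 and AT1G12400. Whether the differences in that stretch are separate from each other was not tested. With 32 added to the unlogged values, AT1G02300 and AT4G12490 stayed past 2-fold, and AT1G01670, PUB19 and AT3G28320 did not. The other 18 of the 36 probe sets past 2-fold, 15 higher and 3 lower, did not name a single gene in the annotation used here. Over all 22746 gene probe sets the arrays correlated at r = 0.995 across probe sets, and 96.3% of the differences lay within 0.5 on the log2 scale. With a floor at the 60th percentile, 16 probe sets were higher and 3 lower, and after adding 32 to the unlogged values 9 were higher and 3 lower.

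**Figure D1:**
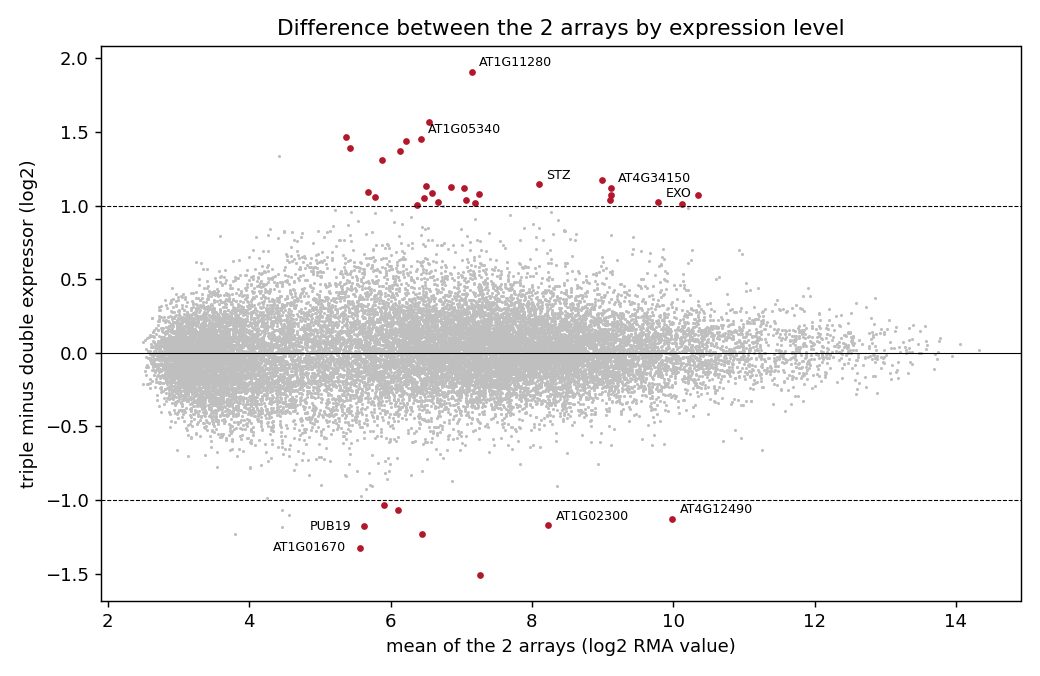
Each point is 1 of 22746 gene probe sets, with the mean of both arrays on the x axis (log2 RMA value) and the triple minus the double expressor on the y axis (log2). Red points are the 28 higher and 8 lower probe sets past the dashed 2-fold lines with the brighter array above the floor. AT1G11280 lies highest, at 1.91.

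Genes known to be induced by low oxygen were slightly higher in the triple expressor. Of 17 named members of the hypoxia list, 13 were higher and 4 lower, with a median difference of 0.21 on the log2 scale, or 1.15-fold. No member reached 2-fold. CML38, a calmodulin-like protein found in hypoxia granules, was at 5.72 in the double expressor and 1.84-fold higher in the triple expressor. Both AT4G10270, a wound-responsive protein gene, and HRA1 (AT3G10040), a trihelix repressor that limits the hypoxia response, lay below the floor on each array, at 4.25 and 4.46 in the double and 5.02 and 4.99 in the triple expressor. With 32 added to the unlogged values their differences were 0.33 and 0.24, and that of CML38 was 0.61. AT4G27450 was 1.32-fold higher at a level of 6.70 in the triple expressor. The lowest member was AT2G17850, at -0.18.

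The median of the hypoxia list lay above 99.9% of 10000 random lists matched on expression level, whose central 95% ran from -0.13 to 0.12. The order-statistic 95% interval of the median over its members was 0.05 to 0.28, which describes spread between genes and not between plants. Among 7 members above the floor the median was 0.22, above 98.2% of such lists. Co-regulated genes are not independent, so these percentiles may overstate how unusual the list is. With 1 array per genotype they describe the 2 arrays only. Of 11 hypoxia genes chosen to be named whatever their values, HRA1 alone had a named probe set. ADH1, PDC1, HRE2, LBD41, PCO1, PCO2, PGB1, SUS1, SUS4 and SAD6 were not analysed here. In the same array the early stress genes STZ and WRKY53 were higher by 1.14 and 0.80, and 3 root hair genes by a median of 0.46.

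The endogenous prolyl 4-hydroxylases, which hydroxylate cell wall proteins in plants, went both ways. Of 8 named members, 4 were higher and 4 lower, the median was 0.01, and it lay at the 54.1 percentile of matched random lists. Over the 6 members above the floor the median was -0.17, at the 2.84 percentile. AT4G25600 went from 6.32 to 5.89, and AT4G33910 and AT1G20270 were each 0.32 lower on the log2 scale. AT5G66060 was 0.30 higher. Glycolytic and fermentative enzymes had a median of 0.04 over 4 named members, at the 61.9 percentile. In that list GAPC2 differed by 0.12, the pyruvate decarboxylase gene PDC2 by -0.12, the lactate dehydrogenase gene AT4G17260 by 0.09 and TPI by -0.01.

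The named flavonoid and anthocyanin genes were lower in the triple expressor. All 5 named members of the list were lower, between -0.68 and -0.37, and the median of -0.44 lay below that of all 10000 random lists. The list holds 17 genes, and the rest, among them CHS, CHI and PAP1, had no named probe set, so the pathway as a whole was not measured. AT5MAT, which adds malonyl groups to anthocyanins, was 1.61-fold lower, from 7.04 to 6.35. UF3GT, an anthocyanin glycosyltransferase, was 1.54-fold lower, from 8.33 to 7.70. The flavonol glycosyltransferases UGT78D1 and UGT78D2 were 1.35-fold and 1.33-fold lower, and the anthocyanin enzyme gene DFR went from 8.66 to 8.29. None of the 5 reached 2-fold.

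Named genes of 2 further lists were higher in the triple expressor. Both named early stress genes were higher, STZ by 1.14 and the transcription factor gene WRKY53 by 0.80 on the log2 scale, and with 2 members that list was given no percentile. All 3 named root hair genes were higher, with a median of 0.46 at the 99.5 percentile. These were the expansins EXPA7, at 0.46, and EXPA18, at 0.40, and the peroxidase gene AT4G26010, at 0.50. The named root markers PYK10 and AT3G01190 differed by 0.16 and 0.27.

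**Figure D2:**
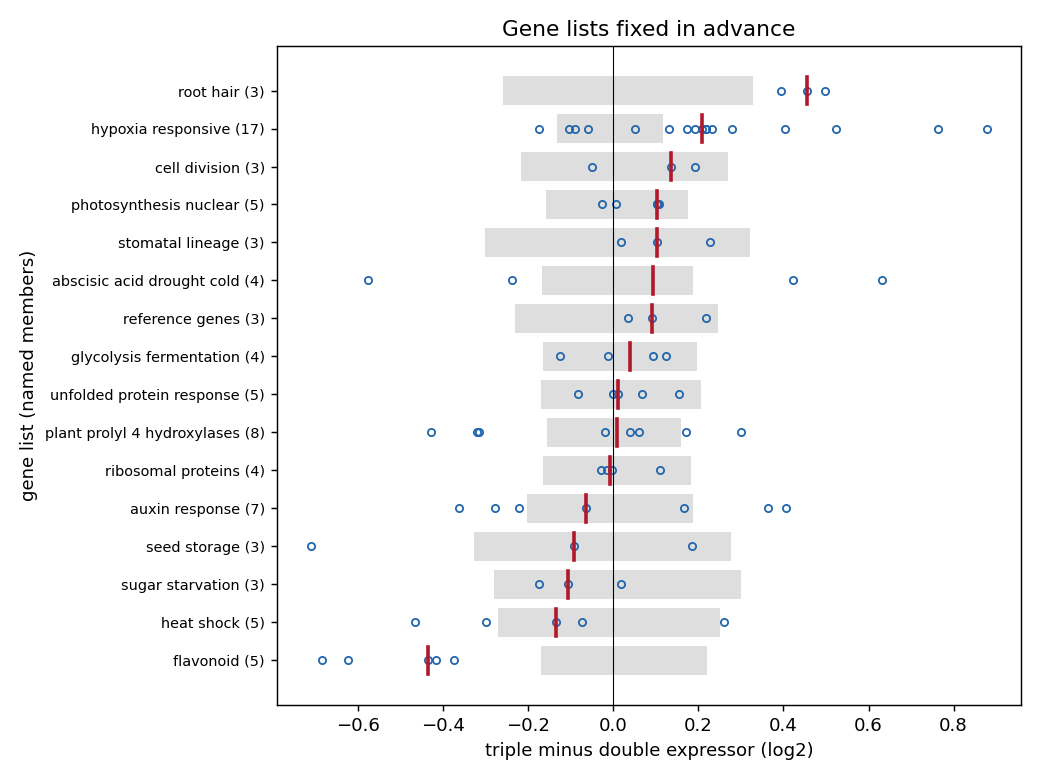
Each circle is a named member of a gene list, placed by the triple minus the double expressor (log2, x axis), for the lists on the y axis with at least 3 named members, whose number is in brackets; the chloroplast list is left out. Red bars are list medians, and grey boxes span the central 95% of medians of matched random lists. The flavonoid median, at -0.44, lies to the left of its box, and those of the hypoxia list, at 0.21, and the root hair list, at 0.46, lie to the right.

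Chloroplast-encoded genes were slightly lower in the triple expressor, with 42 of 69 lower, 26 higher and 1 equal. Their median was -0.05, at the 1.0 percentile of matched lists and at the 8.2 percentile of unmatched lists. The largest differences were those of rpoC1, an RNA polymerase subunit, at -0.56, psbA, which encodes the photosystem II protein D1, at -0.52, rpl20 at -0.47 and petG at -0.42. Nuclear photosynthesis genes had a median of 0.10 over 5 members, at the 82.7 percentile, with LHCB4.2 at 0.11, LHCB4.3 at 0.10, RCA at 0.10 and PRK at -0.03.

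Of 17 lists given a percentile, 4 lay outside the central 95% of random lists, where 0.85 is expected if genes vary independently. Co-regulated genes do not, so the number to expect by chance is not known. The medians of the remaining lists with at least 3 named members lay inside the central 95% of random lists. Heat shock genes had a median of -0.13 over 5 members, with AT5G37670 at -0.47, ATHSP22.0 at -0.30 and AT5G48570 at -0.13, all below the floor, while AT5G51440, the only member above it, was at 0.26. Genes of the unfolded protein response had a median of 0.01 over 5, with BZIP17 at 0.15, CRT1b at -0.08, BZIP28 at 0.07 and ATERDJ3B at 0.01. Abscisic acid, drought and cold genes had a median of 0.09 over 4 members that went both ways: the cold-regulated COR15A and COR15B differed by -0.58 and -0.24, and the dehydrins LTI30 and COR47 by 0.63 and 0.42. Auxin-induced genes had a median of -0.06 over 7, and of 0.17 at the 89.7 percentile over the 3 above the floor, with HAT2 at 0.41, IAA29 at 0.36, GH3.3 at -0.36 and LBD16 at -0.28, of which IAA29 and LBD16 lay below the floor. Sugar starvation genes had a median of -0.11 over 3, with ATL8, below the floor, at -0.17, IVD at -0.11 and MCCA at 0.02. Cytosolic ribosomal protein genes had a median of -0.01 over 4, with AT2G19730 at 0.11, AT5G02870 at -0.03 and AT3G09200 at -0.01. Cell division genes had a median of 0.13 over 3, with TOPII at 0.19, AUR1 at 0.13 and AUR2 at -0.05. Stomatal lineage genes had a median of 0.10 over 3, with MUTE, below the floor, at 0.23, FMA at 0.10 and SPCH at 0.02. Seed storage genes had a median of -0.09 over 3, all below the floor, with the glyoxylate cycle gene ICL at -0.71, PAP85 at 0.18 and OLEO3 at -0.09.

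Lists with 1 or 2 named members are given by their values. Differences were 0.17 for the elongin C gene AT5G59140 and -0.08 for the proteasome subunit gene RPN12a. For iron deficiency they were 0.32 for BHLH101 and 0.03 for PYE, and for oxidative stress 0.46 for GSTU25 and 0.03 for AT2G21640. Jasmonate markers PDF1.2 and THI2.1 differed by -0.12 and -0.13, and glucosinolate genes BCAT4 and AT2G31790 by -0.13 and -0.23. The clock genes AT4G33980, of the morning list, and GI, of the evening list, differed by 0.37 and 0.27. Cytokinin response genes RR16 and ARR15 differed by -0.57 and 0.12, the ethylene genes EIN3 and RTE1 by 0.36 and -0.09, and the gibberellin receptors GID1A and GID1B by -0.07 and 0.03. The senescence regulator WRKY6 differed by 0.16. Of these genes PDF1.2, THI2.1, RR16 and ARR15 lay below the floor on both arrays.

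Reference genes and control probe sets give the level of difference between the arrays where none is looked for. The ubiquitin-conjugating enzyme gene PEX4 differed by 0.04, AT2G28390 by 0.09 and AT4G34270 by 0.22, with a median of 0.09 at the 75.6 percentile. The median difference over all gene probe sets was 0.0. Median centring, which shifts every difference by -0.04, brings PEX4 to about 0.0 but moves that median below it. For 145 loci named by more than 1 probe set, the differences of the brightest and the next probe set correlated at r = 0.10 across loci, and at 0.28 over the 60 loci with these probe sets above the floor. From this comparison the SD per probe set was 0.20 over all and 0.17 above the floor. It measures disagreement between probe sets of a locus on the same 2 arrays. Variation that both probe sets share, such as that of plants, RNA or labelling, is not in it. The array carries 2 versions of the RNA quality and hybridisation controls. The contrast between 3' and 5' probe sets differed between arrays by 0.02 and -0.02 for actin, 0.03 and 0.02 for GAPDH, and -0.04 and -0.14 for ubiquitin. Of 18 bacterial and phage hybridisation controls, 15 were higher and 3 lower on the triple array, with a median of 0.16 and a range of -0.12 to 0.37, and the 25S ribosomal RNA probe set was higher by 0.33.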

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

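The list without CML38 and AT4G10270 was chosen after seeing the data, the other alternatives before. The counts of probe sets past 2-fold depended on the floor, the threshold and the scale. A floor at the 60th percentile gave 16 higher and 3 lower in place of 28 and 8, a 1.5-fold threshold 212 and 76, and the damped scale 9 and 3, each of which by construction keeps fewer or more probe sets. Median centring gave 23 and 9, lowess centring 24 and 8, and no floor 29 and 12. Median centring shifted every difference by -0.04, and lowess centring by -0.03 to 0.04 depending on level. Of 99 recomputed list medians over 17 lists, 2 left the order-statistic interval over the list's members, but for 15 lists that interval is the full range of the members, so this count says little about stability. Both were of the ribosomal protein list, from -0.0081 to -0.0435 under median centring and -0.0318 under lowess centring, by construction of the centring. By size, 2 of the 99 medians moved by more than 0.05, those of the prolyl 4-hydroxylases and the auxin list over members above the floor. The sign of 3 list medians near 0 turned. The prolyl 4-hydroxylase median, 0.01, was -0.17 at the 2.84 percentile over 6 members above the floor and -0.03 under median centring. The auxin median, -0.06, was 0.17 over 3 members above the floor, and that of the unfolded protein response, 0.01, was -0.02 under median centring and -0.0019 under lowess centring. No list median was recomputed on the damped scale. Under the alternatives run, the hypoxia median ranged from 0.17 to 0.23. The flavonoid median ranged from -0.47 to -0.44 and the root hair median from 0.42 to 0.46. Each stayed outside the central 95% of random lists under these alternatives. The chloroplast list, at the 1.0 percentile, lay inside that range, at the 8.2 percentile, against random lists not matched on level. Without CML38 and AT4G10270 the hypoxia median was 0.19 at the 99.7 percentile. Leaving out probe sets named for cross-hybridisation removed no list member, so it says nothing about the lists. Of 764 recomputed values of single genes, 19 moved by more than the spread at their level, all under the damped scale, and 0 genes past 2-fold changed sign. Under that scale CML38 was at 0.61, AT4G10270 at 0.33, HRA1 (AT3G10040) at 0.24 and PUB19 at -0.71. The hypoxia genes AT5G10040 and AT1G33055, below the floor, were at 0.04 and 0.09 in place of 0.21 and 0.22. AT3G10020, above the floor, was at 0.21 in place of 0.22. No replicate could be left out with 1 array per group. No paired analysis was possible because each genotype has 1 array and the labels give no replicate numbers.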

Other observations

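The family scan, the gene order test, the tests of the UGT family, the green tissue test, the early touch test, the families above the floor and the list without CML38 and AT4G10270 were chosen after results were seen. Gene families grouped by symbol showed further shifts. Of 31 families with at least 8 named members, 7 had a median outside the central 95% of matched random lists. If genes vary independently 1.55 is expected, but members of a family may not, so the number to expect by chance is not known. UGT glycosyltransferases, which attach sugars to small molecules, were lower in the triple expressor in 35 of 47 members and higher in 10, with a median of -0.19. UGT71B1 was at -0.64, UGT84A3 at -0.56 and UGT74F1 at -0.48, against UGT73D1 at 0.82 and UGT71C1 at 0.74. All 10 named RALFL genes, which encode secreted peptide signals, were higher, with a median of 0.26 at the 99.99 percentile. RALFL27 was at 0.71, RALFL31 at 0.36 and RALFL33 at 0.31, and 6 of the 10 lay above the floor.

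TBL genes, whose products acetylate cell wall polysaccharides, were higher in 16 of 22 members, with a median of 0.16 at the 99.6 percentile, led by TBL32 at 0.60 and TBL36 at 0.48, while TBL26 was at -0.72. Transcription factors of the BZIP group were higher in 12 of 14, with a median of 0.14, bZIP52 at 0.57 and BZIP53 at 0.53. Glutamate receptor-like genes (GLR) were lower in 6 of 8, with a median of -0.23 and GLR1.4, below the floor, at -0.71. The OTP genes of organelle transcript processing were lower in 7 of 8, with a median of -0.20 and OTP87 at -0.65. The seventh, GH, joins 2 unrelated groups that share a symbol stem, with a median of 0.15. Over members above the floor, UGT and RALFL lay outside the central 95% of random lists and the other 5 families inside it. These were TBL at the 95.1 percentile over 14 members, BZIP at 92.3 over 8, GH at 96.0 over 7, OTP at 3.58 over 4 and GLR at 3.46 over 3. The cell wall families EXPA and XTH, inside that range over all members, were higher in 8 of 10 and 7 of 9 members. EXPA includes the root hair genes EXPA7 and EXPA18. Families outside this theme and inside the range also leaned to a side: ALDH was lower in 8 of 8, CYP lower in 16 of 26 and LCR higher in 8 of 9.

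The higher level of hypoxia-responsive genes in the triple expressor, a median of 0.21 over 17 genes, was weighed against 3 technical or handling explanations. After lowess centring the median was 0.23 at the 100 percentile. The random lists were already matched on level, so this percentile could not decide about an offset between arrays that varies with level. The centring itself moved no value by more than 0.04, so an offset of that size is too small to give the median of 0.21. Members above the floor lay at the 98.2 percentile, which argues against noise of dim probe sets alone, though co-regulation may make that percentile too high. Touch or wounding of the triple seedlings before harvest may also raise such genes: STZ, WRKY53 and CML38 were all higher, but the test needed 3 named early stress genes and had 2, so this stays open, with the list at the 99.7 percentile without CML38 and AT4G10270. The presence of PHD3 is the difference that the design names, and it stays open and untested, since 1 array per genotype cannot part it from any other difference between the seedlings.

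The lower level of flavonoid genes, a median of -0.44 over 5 genes, was -0.45 after lowess centring, at the 0 percentile. With random lists matched on level, that percentile could not decide about a level-dependent offset, but the centring moved no value by more than 0.04. A smaller share of green tissue may also lower photosynthesis genes. The lowest of 5 nuclear photosynthesis genes was PRK at -0.0265, above DFR, the least lowered flavonoid gene, at -0.37. PRK, RCA, LHCB4.1 and LHCB4.2 were bright, between 11.91 and 13.83 on the arrays, while the flavonoid genes lay between 6.35 and 9.09. Whether such bright probe sets can show an equal drop was not tested, so this comparison cannot decide about green tissue. LHCB4.3, at 9.13 in the double expressor, was higher by 0.10, but it alone does not decide either. Other values go with some shift between tissues: 42 of 69 chloroplast-encoded genes were lower, the root hair median was 0.46, and the root markers PYK10 and AT3G01190 were higher by 0.16 and 0.27. Whether a shift between shoot and root contributes stays open, as does PHD3, which was not tested. The labels give both genotypes the same age, medium and lack of treatment.

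The lower level of the UGT family was at the 0 percentile after lowess centring (median -0.17). Random lists were matched on level, so that percentile could not decide about a level-dependent offset. The centring moved no value by more than 0.04. Without the flavonoid UGT genes UGT78D1 and UGT78D2 the family was at the 0 percentile (median -0.17 over 45 genes). Leaving out so few members can barely move a median, yet the 45 remaining genes were still lower as a set. UGT came from the family scan of these same data, so its percentiles are not separate evidence. Over 27 members above the floor the median was -0.19. Probe sets shared between similar UGT genes stay open, because none of the 47 probe sets has a name that marks cross-hybridisation and leaving such names out, at the 0 percentile, changed nothing. A biological difference between the genotypes is open and was not tested.

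Across 12755 adjacent pairs of named loci the correlation of differences was 0.0153. That lay inside the central 95% of 1000 shuffled gene orders, which ran from -0.0175 to 0.0175. This measure says little about a few large differences of both signs in a short stretch. Of the 18 named genes past 2-fold, several lay from AT1G01670 to AT1G12400 on chromosome 1. Higher there were AT1G05340, AT1G06640, AT1G11280, AT1G12010 and AT1G12400, and lower were AT1G01670 and AT1G02300. Whether that stretch holds more than its share was not tested. Differences of at least 0.7 were seen at 1.11% of named loci on chromosome 1, 0.505% on 2, 0.842% on 3, 0.929% on 4 and 0.368% on 5. ORA47, a jasmonate-related transcription factor gene outside the naming rule and chosen after its value was seen, went from 5.60 to 6.49.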
